A study of Mus musculus with 7 samples.

How the data were processed

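Small RNA libraries from the arcuate nucleus of the mouse hypothalamus were analysed in 2 groups, 3 control libraries from mice fed ad libitum and 4 libraries from fasted mice. Per the labels' protocols, RNA was extracted with TRIzol, libraries were made with the NEBNext small RNA kit and size selection kept inserts the length of small RNAs. The labels name arcuate tissue as the source of each sample, while the extraction protocol speaks of an exosome pellet, so the values are described here by their library label only. Per the submitters' processing notes, cutadapt 1.14, Bowtie and the GRCm38 build were used; the counting step, the miRBase release and any filter are not given in the sources used here.

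The deposited table held raw read counts, with no normalization, per pair of mature miRNA and precursor locus, and its annotation placed each miRNA in a canonical or a non-canonical class. The lowest total count in the table was 35 reads. Another 32 lines of the table were not analysed here. For a mature miRNA with several loci the deposited counts repeated much the same reads at each locus: 40 miRNAs took up 112 of the 596 lines, 16 of them had identical counts at all loci, and 35 had locus totals within 1.05-fold of each other. The locus with the highest total was therefore kept for each mature miRNA, which left 524 miRNAs, 406 canonical and 118 non-canonical. This choice was made after the repeated counts were seen. Reads that fit closely related miRNAs, such as members of the let-7 family, miR-7a-5p and miR-7b-5p, or miR-486a-5p and miR-486b-5p, could have been split between them by the counting, so their separate values are uncertain.

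Total counts over the 524 miRNAs were 6703926, 7119700 and 5720441 in control replicates 1 to 3, and 2131905, 6630476, 2149235 and 3017366 in fasted replicates 1 to 4. A count of 3, taken as the floor of detection, corresponded to between 0.421 and 1.41 CPM, counts scaled to a common library total. Intervals given for a share of counts in 1 library are 95% Wilson intervals, and they and the floor cover counting error only, since reads amplified by PCR are not independent molecules. No pair of libraries within a group agreed within sampling noise: the chi-square per degree of freedom lay between 109.87 and 1166.5. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

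Fasted and control libraries were compared with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) on the deposited counts, with TMM scaling, the default expression filter, which kept 503 miRNAs, and Benjamini-Hochberg adjustment at 0.05. The SE of an edgeR log2 fold change was derived from the test, as its absolute value over the square root of the F statistic. Bounds in SE therefore restate that statistic. TMM factors were 1.14, 1.35 and 1.20 in the control libraries and 0.859, 0.550, 0.964 and 1.18 in the fasted libraries. The low factor of fasted replicate 2 lifts its scaled CPM, so that the scaled value of miR-7a-5p there was 1058420 CPM. The common biological coefficient of variation was 0.260. Lists of miRNAs were tested with camera in limma 3.58.1 with a preset correlation of 0.01, then with an estimated correlation, and with fry, each adjusted over the 18 lists that had at least 3 tested members. Single quantities were compared with an exact two-sided permutation test on the absolute difference of means over the 35 splits of the 7 libraries, for which 0.0286 is the smallest possible p. Precursor positions in GRCm38 were taken from the deposited table and set against GENCODE release M21 (GRCm38), in which 410 of 411 precursor loci overlapped a miRNA gene on the same strand. Mature sequences were also searched for exact matches in the GENCODE transcripts.

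The groups, tests, 19 lists, the rule for named miRNAs and most alternatives were chosen before the data were examined. The rule took every measured miR-7 family member, the 5 miRNAs with the smallest p in each direction where fewer than 5 passed, the 5 most abundant miRNAs, and the 2 members of each list with the smallest p. The lists were the miR-7 family, miRNAs from the literature on hypothalamic feeding control, neuron, oligodendrocyte, microglia and leukocyte, erythrocyte, endothelial and mural, and ependymal and choroid plexus miRNAs, activity-regulated miRNAs, the Dlk1-Dio3 cluster, pituitary and epithelial miRNAs, the miR-183 cluster, the Hox clusters, miRNAs of muscle, liver, gut and skin, and the let-7, miR-29, miR-30, miR-181 and miR-17-92 families.

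The procedure was tested on simulated data in which known changes were added to the 503 miRNAs of the fasted against control comparison in 10 draws. At an adjusted p of 0.05 it called 21.8% of miRNAs changed 1.5-fold, 65.7% of those changed 2-fold and 97.0% of those changed 4-fold, and 1.19% of unchanged miRNAs. Over these draws 670, 670 and 660 miRNAs changed by those sizes stood beside 3030 unchanged ones. The adjustment is looser where many miRNAs change, so these rates may be too high for the real comparison. In 10 draws with no change the procedure called 1 miRNA and 1 of 180 lists, and a list raised 2-fold was called in 10 of 10 draws. Each miRNA was drawn independently, so these list rates do not cover lists whose members vary together. In the data the let-7 family had an estimated correlation of 0.90. Alternatives covered DESeq2 size factors, total counts only, other expression filters, limma voom, the DESeq2 1.42.0 Wald test, other thresholds, leaving out each library, and a block for the replicate number without fasted replicate 4. Others were added after the data were seen: lines as deposited, counts summed over loci, 1 entry per mature sequence, canonical miRNAs only, removal of a GC trend, thinning of every library to the shallowest, and numbers of miRNAs expected at that depth.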

Results

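The libraries measured small RNAs of the arcuate nucleus, the hypothalamic region that holds the AgRP neurons, which promote feeding, and the POMC neurons, which restrain it. There were 3 control libraries from mice fed ad libitum and 4 from fasted mice, with 5720441 to 7119700 counts per control library and 2131905 to 6630476 per fasted library over 524 mature miRNAs. The labels do not settle whether the RNA came from whole tissue or from an exosome pellet. All 524 miRNAs had at least 1 count in each control library, against 521.5 ± 3.70 (SD, n = 4) in fasted libraries (exact permutation p = 0.371). No library could hold more than these 524, so this test could show only fewer miRNAs in fasted libraries. The mean total count was 6514690 ± 718568 (SD, n = 3) in control and 3482250 ± 2139140 (SD, n = 4) in fasted libraries, which was not separated by the exact permutation test (p = 0.0857, adjusted 0.129 over 3 quantities).

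The study asked which arcuate miRNAs differ between fasted and fed mice and took miR-7a-5p as its focus. miR-7a-5p was the most abundant miRNA in these libraries and made up 29.8% ± 1.88 of all counts in control (SD, n = 3) and 45.3% ± 8.75 in fasted libraries (SD, n = 4). Its share was higher in each of the 4 fasted libraries than in any control library: the control libraries lay between 27.61% (95% Wilson interval 27.58 to 27.64) and 30.99% (30.95 to 31.02), and the fasted ones between 39.20% (39.15 to 39.26) and 58.25% (58.22 to 58.29). miR-7b-5p, encoded by a separate gene, made up 6.21% ± 0.906 in control (n = 3) and 10.1% ± 2.52 in fasted libraries (SD, n = 4; exact permutation p = 0.0857, adjusted 0.107). For the 3p arms of the miR-7a hairpins, miR-7a-1-3p was at 10.7 ± 1.38 scaled CPM in control and 9.18 ± 2.17 in fasted libraries, and miR-7a-2-3p at 26.1 ± 2.18 and 25.6 ± 5.64 (SD, n = 3 and 4).

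For the share of miR-7a-5p the exact permutation test gave p = 0.0286, the smallest that 35 splits allow, and 0.0476 after adjustment over 5 shares, which were chosen after the values were seen. The adjusted value is this low only because the shares of miR-148a-3p and miR-99a-5p reached the same p. All shares are parts of 1 total, so a rise of miR-7a-5p lowers the others. In the test fixed beforehand, miR-7a-5p had a log2 fold change of 1.25 (SE 0.42) and miR-7b-5p of 1.36 (SE 0.42), and neither passed among the 503 miRNAs tested (edgeR adjusted p = 0.208 and 0.151). The exact permutation p on log2 CPM was 0.0571 for each. Of the 4 family members tested, 2 passed when adjusted over the list alone, miR-7a-5p and miR-7b-5p (edgeR adjusted p = 0.0213 for each). This is not taken as independent evidence, because the study had miR-7a-5p as its focus and may have chosen it on these samples. Adjusted over the list alone, neither passed when control replicate 1, 2 or 3 or fasted replicate 2 was left out (edgeR adjusted p = 0.0511 to 0.113) or with total counts only (0.104 for each). The log2 fold changes of miR-7a-1-3p and miR-7a-2-3p were -0.19 (SE 0.28) and -0.01 (SE 0.24). As a list the family averaged 0.60 and did not pass (camera adjusted p = 0.218; 0.967 with an estimated correlation), with a mean of 0.29 without fasted replicate 2. Without fasted replicate 2 the log2 fold change of miR-7a-5p was 0.77 (SE 0.30) and that of miR-7b-5p 0.86 (SE 0.31). With total counts only they were 0.61 (SE 0.31) and 0.71 (SE 0.33). With the DESeq2 Wald test miR-7a-5p passed, with a log2 fold change of 1.23 and an adjusted p of 0.0188, where its 20 alternatives ranged from 0.0188 to 0.512, and miR-7b-5p passed at 1.34 (0.0188, range 0.0188 to 0.444).

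In GRCm38 the mature miR-7a-5p comes from 2 precursors, mir-7a-1 on chromosome 13 (58392779 to 58392886, minus strand), in an intron of Hnrnpk on the same strand, and mir-7a-2 on chromosome 7 (78888277 to 78888373, plus strand), outside other annotated genes. The mir-7b precursor lies on chromosome 17 (56242988 to 56243098, plus strand), also outside other genes. Counts at the 2 miR-7a loci repeat the same reads, so they cannot be assigned to either precursor.

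**Figure D1:**
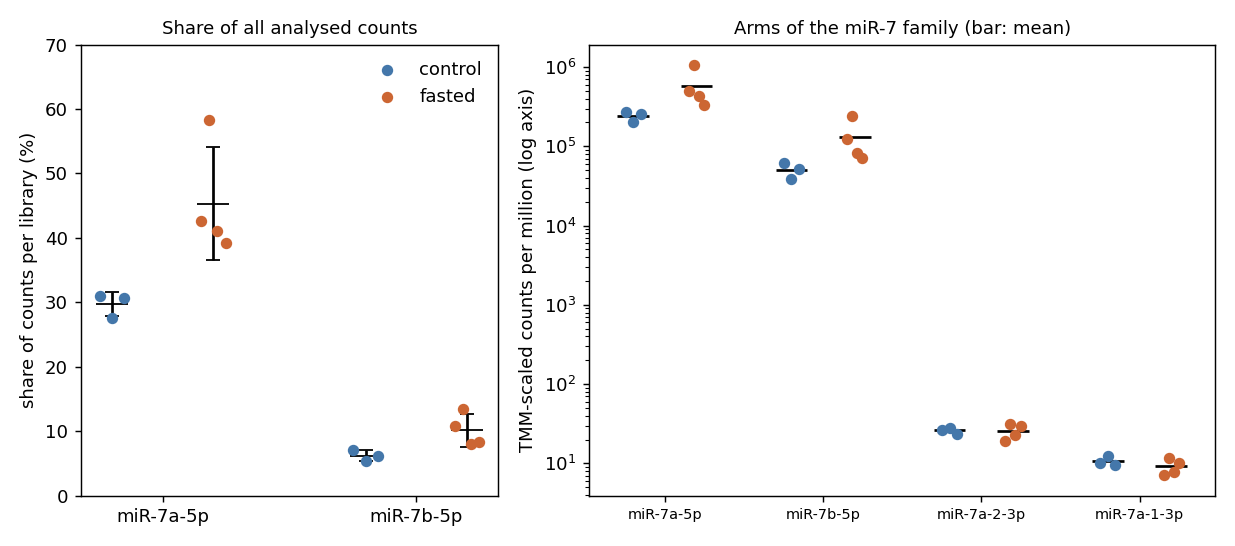
Left, share of all analysed counts (%) taken by miR-7a-5p and miR-7b-5p in each of 3 control and 4 fasted libraries, with the mean and SD. Right, TMM-scaled CPM on a log axis for the 4 measured arms of the family, each point a library and each bar a mean; miR-7a-5p lies between 39.20% and 58.25% in fasted and between 27.61% and 30.99% in control libraries, while both 3p arms overlap between groups.

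Across all miRNAs, miR-6240 and miR-690 rose in fasted libraries. miR-6240 averaged 2.80 ± 1.98 scaled CPM in control (SD, n = 3) and 15.9 ± 6.10 in fasted libraries (SD, n = 4), a log2 fold change of 2.51 (SE 0.45; edgeR adjusted p = 0.0332). miR-690 averaged 30.7 ± 20.3 in control and 228 ± 197 in fasted libraries (SD, n = 3 and 4), a log2 fold change of 2.89 (SE 0.58; edgeR adjusted p = 0.0496). The log2 fold change of miR-690 was 2.12 (SE 0.44) without fasted replicate 1 and 3.55 (SE 0.68) without control replicate 1, and that of miR-6240 was 3.23 (SE 0.46) without control replicate 1. Both were higher in each of the 4 fasted libraries than in any control library, and both belong to the class that the deposited table calls non-canonical. The miR-6240 precursor lies on chromosome 5 (114851948 to 114852064, plus strand) outside other genes, and the miR-690 precursor on chromosome 16 (28599935 to 28600043, minus strand) in an intron of Fgf12 on the same strand. The mature miR-690 sequence also occurs exactly in the transcripts of 19 annotated genes, so its reads cannot be tied to that locus. That of miR-6240 occurred in 1 annotated gene, but neither the genome nor full-length ribosomal RNA was searched, so other sources of its reads were not excluded.

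Other miRNAs with small p in the higher direction were miR-3535 (log2 fold change 1.09, SE 0.26, edgeR adjusted p = 0.0890), whose precursor overlaps an exon of Ncl and a small nucleolar RNA on the same strand, miR-6238 (2.43, SE 0.66) and miR-296-5p (1.27, SE 0.35). miR-6238 lay near the floor of detection in control libraries, at 0.583 to 1.43 scaled CPM. It was at 0.483 in fasted replicate 3 and at 3.09 to 11.5 in the other fasted libraries. In the lower direction miR-151-3p, from an intron of Ptk2, averaged 1648 ± 280 scaled CPM in control and 888 ± 63.2 in fasted libraries (log2 fold change -0.89, SE 0.20, edgeR adjusted p = 0.0697). miR-425-5p was at -0.87 (SE 0.21, edgeR adjusted p = 0.0890). miR-98-3p was at -1.78 (SE 0.46), near the floor in fasted libraries with 0.562 to 1.64 scaled CPM. miR-3968 was at -2.27 (SE 0.61), or -0.60 without control replicate 2, and miR-704 at -1.35 (SE 0.37). None of these 8 passed in this test, but each passed under at least 1 alternative. With DESeq2 these were miR-151-3p, miR-3535, miR-425-5p, miR-6238 and miR-296-5p, and with total counts only miR-151-3p, miR-425-5p, miR-98-3p, miR-3968 and miR-704. With total counts only the median of all miRNAs was -0.45, against 0.04 with TMM, a shift in the direction of the calls gained there. Without fasted replicate 3, miR-3535 and miR-6238 passed, and at a mean CPM of at least 10, miR-151-3p. Over the alternatives the adjusted p of miR-151-3p ranged from 0.00516 to 0.222 and that of miR-3968 from 9.1e-05 to 0.566. At an unadjusted p under 0.05 there were 31 miRNAs higher and 33 lower. The groups did not overlap for 64 miRNAs, 26 higher and 38 lower in fasted libraries, where chance gives 5.71% of the 503. The calls of miR-6240 and miR-690 were both lost when control replicate 2 or 3 or fasted replicate 1 or 2 was left out, with 0 changed miRNAs in edgeR each time and 42 to 60 at an unadjusted p under 0.05. That of miR-690 was also lost without control replicate 1 (edgeR adjusted p = 0.0640). The count reached 4 without fasted replicate 3. With DESeq2 9 miRNAs passed, 7 higher and 2 lower, and with total counts only 9 passed, 2 higher and 7 lower.

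**Figure D2:**
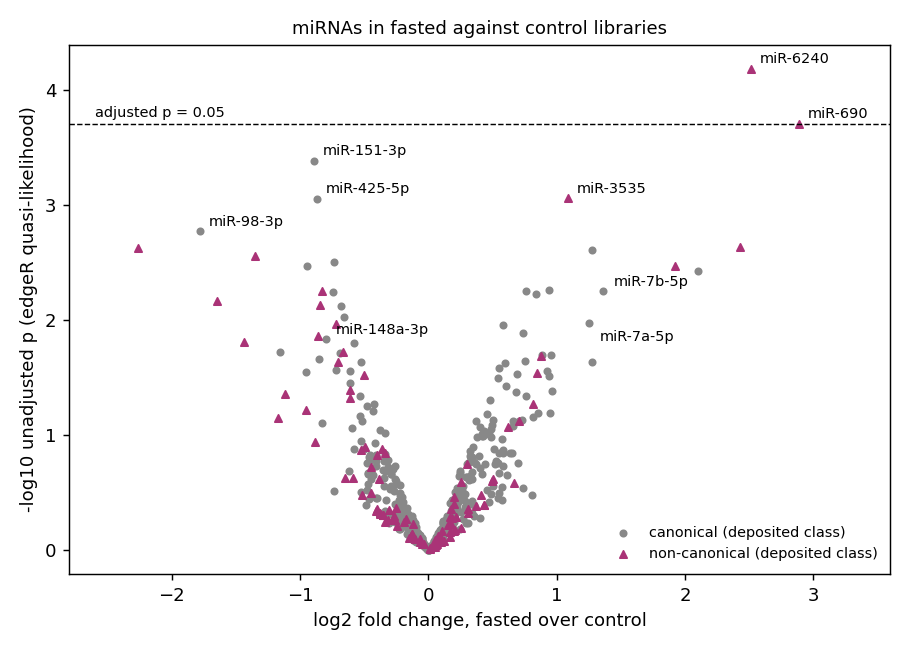
Log2 fold change of fasted over control libraries against -log10 of the unadjusted edgeR p for 503 miRNAs, with triangles for the class deposited as non-canonical and circles for canonical miRNAs. The dashed line marks the adjusted p of 0.05, which only miR-6240 and miR-690 reach, while miR-7a-5p and miR-7b-5p lie below it.

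Among the most abundant miRNAs, miR-148a-3p made up 15.0% ± 3.01 of counts in control (SD, n = 3) and 6.28% ± 2.43 in fasted libraries (SD, n = 4), and miR-99a-5p 9.38% ± 1.08 and 4.45% ± 1.40. For both shares the exact permutation p was 0.0286 and the adjusted value 0.0476, again with shares chosen after the values were seen. Shares are parts of the same total, so these falls are not independent of the rise of miR-7a-5p. That rise, from 29.8% to 45.3%, by itself shrinks the other shares by a smaller proportion than these falls. The part beyond it was not tested as a share. On the TMM scale their log2 fold changes were -0.79 (SE 0.29) and -0.61 (SE 0.26), and neither passed (edgeR adjusted p = 0.248 and 0.322), although miR-148a-3p did with total counts only, at -1.26 (0.0373, where its 20 alternatives ranged from 0.0373 to 0.659). miR-127-3p, of the imprinted Dlk1-Dio3 cluster, was at 0.51 (SE 0.32). The 10 most abundant miRNAs held 77.5% ± 1.21 of counts in control and 82.9% ± 4.37 in fasted libraries (SD, n = 3 and 4; exact permutation p = 0.0857, adjusted 0.129). Non-canonical miRNAs held 2.18% ± 0.226 and 1.51% ± 0.601 (exact permutation p = 0.143).

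All 9 tested members of the let-7 family, regulators of developmental timing, had positive log2 fold changes, with a mean of 0.64, and 6 of the 9 did with total counts only. The list passed with a preset correlation (camera adjusted p = 0.00121) but not with an estimated correlation (adjusted p = 0.967). Its leading members by p were miR-98-5p at 0.89 (SE 0.34) and let-7e-5p at 0.92 (SE 0.38). In the list from the feeding literature 10 of 12 members were positive (7 with total counts only), with a mean of 0.57, and this list too passed with a preset correlation (camera adjusted p = 0.00879) but not with an estimated correlation (adjusted p = 0.967). Its members with the smallest p were miR-384-3p at 0.76 (SE 0.23) and miR-7b-5p, and the mean log2 CPM of this list was 7.59 in fasted replicate 1 and 8.46 to 8.56 in the other fasted libraries. The fry test called no list (lowest adjusted p = 0.741, and 0.491 in either direction). In the let-7 list 0 of 9 members passed over all miRNAs and 0 adjusted over the list alone. In the feeding list 0 passed over all and 3 adjusted over the list alone, miR-384-3p, miR-7b-5p and miR-7a-5p. All 3 were lost when control replicate 1, 2 or 3 or fasted replicate 1 or 2 was left out, and with total counts only. miR-7a-5p was also lost with lines as deposited, with summed loci and with the GC trend removed (edgeR adjusted p = 0.0529, 0.0502 and 0.0654 over the list alone). The feeding list shares miR-7a-5p, the focus of the study, and miR-7b-5p with the miR-7 family, and miR-141-3p, miR-200a-3p, miR-200b-3p and miR-429-3p with the pituitary and epithelial list. Without fasted replicate 1 the let-7 call was lost (camera adjusted p = 0.0503), and without control replicate 1 or 3 the feeding list call was lost (means 0.44 and 0.47; 0.140 and 0.0815). Without control replicate 2 the mean of the feeding list was 0.93. With total counts only the means were 0.11 for let-7 and 0.06 for the feeding list, where the median of all miRNAs was -0.45. Both lists still passed there with the preset correlation (camera adjusted p = 0.00141 for each). Neither did with an estimated correlation (camera adjusted p = 0.996 for let-7 and 0.806 for the feeding list).

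Lists of cell types that arcuate tissue or its surroundings hold did not pass. For neuron-enriched miRNAs 6 of 10 members were positive, with a mean of 0.11 (camera adjusted p = 0.746), miR-124-3p at 0.54 (SE 0.23) and miR-124-5p at 0.47 (SE 0.27). Oligodendrocyte miRNAs averaged 0.13 over 4 members (adjusted p = 0.932), with miR-338-3p at 0.34 (SE 0.22) and miR-219a-2-3p at -0.10 (SE 0.18). Microglia and leukocyte miRNAs averaged 0.0073 over 5 members (0.969), with miR-142a-3p at 0.28 (SE 0.34) and miR-142a-5p at -0.30 (SE 0.28); their mean and their camera direction differed in sign. Erythrocyte miRNAs averaged 0.04 over 3 members (0.969), with miR-486a-5p at 0.05 (SE 0.30) and miR-486b-5p at 0.04 (SE 0.30). Endothelial and mural miRNAs averaged 0.26 over 6 members (0.529), with miR-145a-5p at 0.66 (SE 0.35) and miR-126a-3p at -0.38 (SE 0.21), and passed without control replicate 2 with the preset correlation (mean 0.53, 0.0402; adjusted p = 0.653 with an estimated correlation). Their mean was 0.14 without control replicate 1 and also without control replicate 3. Ependymal and choroid plexus miRNAs averaged -0.08 over 7 members (0.932), with miR-204-5p at 0.24 (SE 0.19) and miR-34b-3p at -0.43 (SE 0.34).

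Pituitary and epithelial miRNAs averaged 0.53 over 7 members, 6 of them positive (camera adjusted p = 0.257), with miR-200c-3p at 0.96 (SE 0.43) and miR-375-3p at 0.32 (SE 0.21). Their mean was 1.39 without control replicate 2 and 0.78 without fasted replicate 1, and the list passed in both cases with the preset correlation (camera adjusted p = 0.000333 and 0.00288) but not with an estimated correlation (adjusted p = 0.653 and 0.913). It also passed with total counts only (mean 0.060, camera adjusted p = 0.0149; adjusted p = 0.996 with an estimated correlation), and its 13 alternatives ranged from 0.000333 to 0.897. The mean was 0.23 and 0.27 without control replicates 1 and 3, and 0.28 and 0.29 without fasted replicates 3 and 4. The miR-183 cluster of sensory organs averaged 0.50 over 3 members (0.746), with miR-182-5p at 0.55 (SE 0.53) and miR-183-5p at 0.48 (SE 0.47), the latter at 6.01 scaled CPM in fasted replicate 1 and 36.4 to 46.3 in the other fasted libraries. Without that replicate the cluster passed with the preset correlation (mean 0.83, 0.0191; adjusted p = 0.913 with an estimated correlation). Its mean was 0.28, 1.16 and 0.23 without control replicates 1, 2 and 3, and 0.23 without fasted replicate 3. Of the miRNAs of muscle, liver, gut and skin, 4 of 7 were positive, with a mean of 0.29 and a median of 0.00082 (0.932), and 1 passed adjusted over the list alone, miR-205-5p of epithelia, at 2.10 (SE 0.61), with 0.391, 2.18 and 0.583 scaled CPM in control replicates 1 to 3. miR-205-5p thus lay near the floor of detection in control replicates 1 and 3, and the groups overlapped, with 1.92 scaled CPM in fasted replicate 2. Its value was 3.24 (SE 0.70) without control replicate 2 and 1.63 (SE 0.66) without fasted replicate 4, and adjusted over the list alone it did not pass without control replicate 1 or 3 or fasted replicate 3 or 4 (edgeR adjusted p = 0.0618 to 0.185); miR-133a-3p was at 0.73 (SE 0.38). Of the Hox clusters only miR-10b-5p, at 0.68 (SE 0.30), and miR-10a-5p, at 0.06 (SE 0.24), were tested, too few for a list test.

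Activity-regulated miRNAs averaged -0.04 over 5 members with a median of 0.07 (camera adjusted p = 0.932), with miR-132-5p at -0.53 (SE 0.21) and miR-212-3p at 0.17 (SE 0.23). The Dlk1-Dio3 cluster, 53 of 81 arms positive, averaged 0.11 (0.529), with miR-299a-5p at 0.95 (SE 0.36) and miR-410-5p at 1.27 (SE 0.50). The miR-29 family averaged 0.14 over 3 members (0.874), with miR-29a-3p at 0.21 (SE 0.20) and miR-29b-3p at 0.11 (SE 0.23), and the miR-30 family 0.22 over 5 members (0.518), with miR-30e-5p at 0.37 (SE 0.19) and miR-30d-5p at 0.27 (SE 0.24). The miR-181 family averaged 0.05 over 4 members with a median of -0.0031 (0.95), with miR-181d-5p at 0.24 (SE 0.19) and miR-181c-5p at -0.04 (SE 0.23). The miR-17-92 family and its paralogs averaged 0.08 over 7 members (0.988), with miR-19b-3p at 0.95 (SE 0.47) and miR-25-3p at -0.34 (SE 0.22). With total counts only the median of all miRNAs moved to -0.45 from 0.04, and the means of 11 of the 18 lists changed sign.

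**Figure D3:**
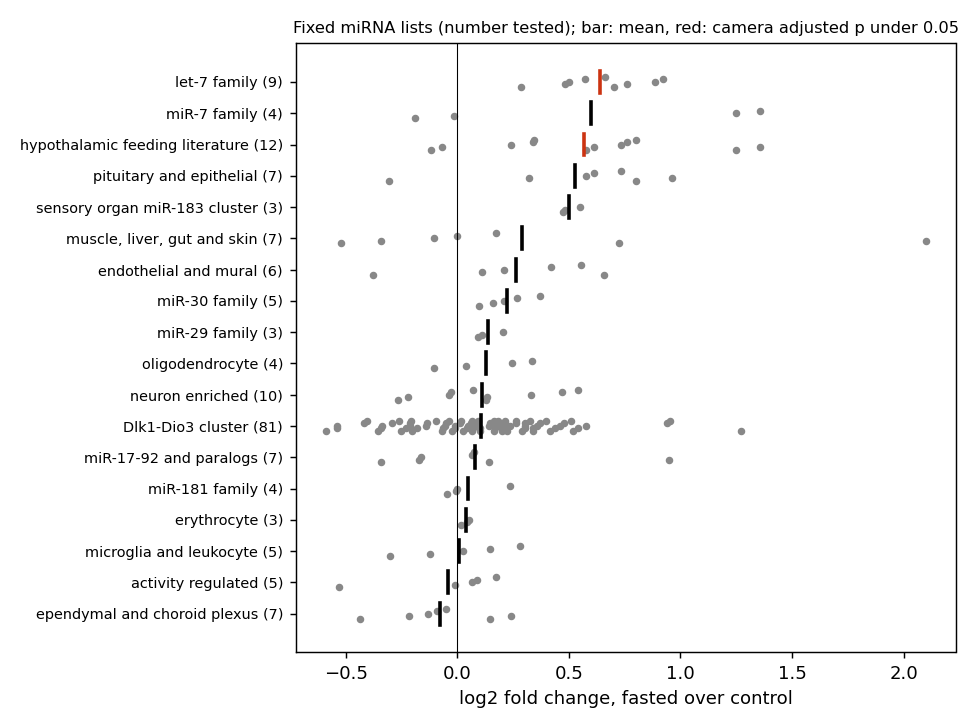
Log2 fold change of fasted over control libraries for the tested members of 18 lists, each grey point a miRNA and each bar the mean of a list, red where the camera adjusted p with a preset correlation was under 0.05. Only the let-7 family, with a mean of 0.64, and the feeding literature list, with a mean of 0.57, are red, and neither passed with an estimated correlation (adjusted p = 0.967 for each).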

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

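The tests of total counts and of the whole non-canonical class and the count of splits at an unadjusted p were chosen only after the result was seen. In 7 of 80 groups of 4 fasted values, 1 library lay further from the others than Dixon's 95% critical gap for 4 samples, taken as a share of the range, where chance gives about 4. For single miRNAs the gap was taken on the log2 of scaled CPM plus 1, so it does not follow from the scaled CPM printed beside it. miR-3968 was highest in fasted replicate 2 (10.4 scaled CPM against 5.79 to 6.01 in the others, gap 0.940), and miR-142a-5p lowest there (8.49 against 10.4 to 10.7, gap 0.874). The share of miR-99a-5p was lowest there too (2.37% against 4.87% to 5.34%, gap 0.841), and the mean log2 CPM of the miR-7 family was highest there (11.7 against 10.7 to 10.8, gap 0.88). In fasted replicate 1, miR-183-5p was lowest (6.01 against 36.4 to 46.3, gap 0.877), as were the number of miRNAs detected (516 against 523 to 524, gap 0.875) and the mean log2 CPM of the feeding list (7.59 against 8.46 to 8.56, gap 0.895).

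miR-7a-5p and miR-7b-5p were both higher in fasted libraries, with 1.25 (SE 0.42) as the lower log2 fold change of the pair, and fasting, the design's own explanation, is not excluded by any test. For TMM scaling as the whole cause, the lower value with total counts only was 0.61 (SE 0.31, edgeR adjusted p = 0.302). It exceeded 0 by more than 1 SE, a bound set after the result was seen, but not by the 2 SE asked of the GC and single-library tests. TMM scaling as the whole cause was thus not decided, and scaling sets much of the size. A GC trend per library is argued against by a lower value of 1.11 (SE 0.40) once the trend was removed. A single fasted library as the whole cause is argued against by a lowest value of 0.77 (SE 0.30), reached without fasted replicate 2. Neither miRNA passed after adjustment over all miRNAs in edgeR, although both did with the DESeq2 Wald test (adjusted p = 0.0188 for each). Chance therefore stays open too, and a response to fasting may explain the pattern only as a hypothesis.

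miR-6240 and miR-690, the only miRNAs past the threshold, are both in the non-canonical class, and 4 of the 35 splits of the 7 libraries gave as many miRNAs past it as the real split, which gave 2; the highest other split gave 8, so chance cannot be excluded. At an unadjusted p under 0.05 the real split gave 64, and 2 of the 35 splits gave as many, the other with 70, which does not exclude chance either. That other split set fasted replicates 1, 2 and 4 against the rest, so it moved only fasted replicate 3 from the real grouping. The split with 8 set control replicates 1 and 3 with fasted replicate 1 against the rest and may reflect a structure of the samples other than the groups, which was not tested, although at an unadjusted p under 0.05 it gave 38, fewer than the real split. A rise of the whole class is argued against by its median log2 fold change, which was -0.12 relative to the canonical miRNAs. After every library was thinned to the shallowest, the lower value of the pair was 2.39 (SE 0.50), which met the bound set beforehand against a difference in depth. Thinning keeps the proportions of each library, so that bound could hardly fail, and a cause tied to depth was not decided. Neither miRNA passed after thinning (edgeR adjusted p = 0.0553 for each). Fragments of other small RNAs stay open: 14 miRNAs inside annotated small RNA genes had a median -0.17 relative to the rest, and a value of 0 or less had been set beforehand as evidence against, but neither miR-6240 nor miR-690 is in that set, so the bound did not bear on them. For the lists, 16 of the 35 splits gave as many past the threshold as the real split, which gave 2, and the highest other gave 6, so chance cannot be excluded there either.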

How the results depend on the processing

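Lines as deposited, counts summed over loci, canonical miRNAs only, 1 entry per sequence, the GC trend, thinning and numbers of miRNAs at the depth of the shallowest library were chosen only after the data were seen. The number of changed miRNAs, 2, was 1 with DESeq2 size factors, 1 with limma voom, 1 with summed loci, 9 with total counts only (2 higher, 7 lower), 9 with DESeq2 (7 higher, 2 lower), and 0 with lines as deposited, with canonical miRNAs only, with the GC trend removed and after thinning. At those settings with 0 calls, between 45 and 71 miRNAs had an unadjusted p under 0.05. The count was 5 at an adjusted p of 0.10 and 56 at an unadjusted p of 0.05 with a 1.5-fold change. Leaving out 1 library gave 0 to 4: 0 without control replicate 2 or 3 or fasted replicate 1 or 2 (42 to 60 at an unadjusted p under 0.05), 1 without control replicate 1, and 4 without fasted replicate 3. miR-6240 passed in 11 of 18 alternatives and miR-690 in 8 of 19. miR-7a-5p was higher in 20 of 20 alternatives and passed in 1, DESeq2 (1.23, adjusted p = 0.0188; range 0.0188 to 0.512); leaving out 1 library gave 0.77 to 1.45. The number of lists past the threshold, 2, ranged from 1 to 4 when 1 library was left out: 1 without control replicate 1 or 3, and 4 without control replicate 2. Of miRNAs with a count of at least 10 the fasted libraries held fewer on average (a difference of -99.9; exact permutation p = 0.0286), at unequal depth. At the depth of the shallowest library the difference was -31.7 (402 and 370; exact permutation p = 0.143), and of miRNAs with a count of at least 1 there were 522 and 517. The cause of these changes was not tested, beyond the fewer libraries or miRNAs that some settings leave.

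With total counts only the median of all miRNAs was -0.45, so that 15 of 51 miRNAs and 11 of 18 lists, none of them past the threshold with TMM, changed sign: miR-30e-5p -0.086, miR-124-5p -0.040, miR-375-3p -0.16, miR-338-3p -0.15, miR-204-5p -0.24, miR-181d-5p -0.22, miR-30d-5p -0.24, miR-29a-3p -0.26, miR-183-5p -0.0051, miR-142a-3p -0.20, miR-212-3p -0.34, miR-29b-3p -0.42, miR-10a-5p -0.36, miR-486a-5p -0.38 and miR-486b-5p -0.39. The list means were neuron -0.41, Dlk1-Dio3 -0.39, oligodendrocyte -0.38, microglia -0.51, erythrocyte -0.40, endothelial -0.23, muscle, liver, gut and skin -0.18, miR-29 -0.36, miR-30 -0.28, miR-181 -0.41 and miR-17-92 -0.43. Other reversals were miR-181c-5p (0.0020 with the GC trend removed, 0.14 after thinning), miR-7a-2-3p (0.061 with the GC trend removed), the microglia list (-0.0069 with DESeq2 size factors, -0.073 with limma voom, -0.073 at a mean CPM of at least 10), the erythrocyte list (-0.074 without a filter), and, at a mean CPM of at least 10, the muscle, liver, gut and skin list (-0.19, from 0.29) and the miR-17-92 list (-0.12).

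Leaving out 1 library gave these ranges where a sign changed: miR-212-3p -0.0080 to 0.26, miR-29b-3p -0.052 to 0.24, miR-10a-5p -0.088 to 0.22, miR-181c-5p -0.16 to 0.036, miR-486a-5p -0.18 to 0.41, miR-486b-5p -0.20 to 0.39, miR-7a-2-3p -0.14 to 0.097, and the lists of activity-regulated -0.13 to 0.11, microglia -0.11 to 0.15, erythrocyte -0.17 to 0.32, ependymal -0.18 to 0.0037 and miR-17-92 miRNAs -0.017 to 0.15. Among values that passed neither with all libraries nor with 1 library left out, these also kept their sign but moved by over 1.5 times on the log2 scale: miR-10b-5p 0.43 to 0.90, miR-127-3p 0.20 to 0.71, miR-142a-3p 0.14 to 0.54, miR-142a-5p -0.47 to -0.15, miR-145a-5p 0.38 to 1.21, miR-182-5p 0.15 to 1.27, miR-183-5p 0.20 to 0.97, miR-19b-3p 0.61 to 1.19, miR-200c-3p 0.65 to 1.71, miR-219a-2-3p -0.18 to -0.071, miR-25-3p -0.46 to -0.21, miR-29a-3p 0.13 to 0.26, miR-30d-5p 0.15 to 0.35, miR-34b-3p -0.73 to -0.22, miR-375-3p 0.19 to 0.41, miR-410-5p 0.84 to 1.54 and miR-7a-1-3p -0.35 to -0.075, and the list means Dlk1-Dio3 0.045 to 0.14, miR-181 0.019 to 0.074, miR-29 0.045 to 0.23, miR-30 0.11 to 0.33, muscle, liver, gut and skin 0.15 to 0.44, neuron 0.0044 to 0.17 and oligodendrocyte 0.030 to 0.21.

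Replicate numbers 1 to 3 occur in both groups, but the deviations of same-numbered libraries correlated at 0.05, 0.06 and -0.30, so the numbers were not taken to pair them, and not every library correlated best with its own number. The block fit also left out fasted replicate 4, whose number no control library has. Its differences from the main fit therefore cannot be credited to the block alone. With the number as a replicate block 5 miRNAs passed (miR-6240, miR-690, miR-3535 and miR-6238 higher, miR-3968 lower) and 3 lists, let-7, feeding and the miR-7 family (mean 0.60, camera adjusted p = 0.0339, range over 13 alternatives 0.0339 to 0.436), none of which passed with an estimated correlation (adjusted p = 0.988 for each); miR-7a-5p was at 1.33 and did not pass, miR-205-5p no longer passed adjusted over its list alone (1.72, edgeR adjusted p = 0.0604), and miR-181c-5p (0.012), the activity list (0.012) and the microglia list (-0.12) changed sign.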

Other observations

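The test of the miR-7a arms against each other and the search for copies of mature sequences were chosen only after the result was seen. The mature sequence of miR-690 occurred exactly in transcripts of 19 annotated genes, 16 of them miRNA genes and 3 others, whereas that of miR-6240 occurred in 1. Neither the genome nor full-length ribosomal RNA was searched, so this single match does not show that the miR-6240 sequence is unique. Among 524 mature miRNAs the median was 1 gene, and 1 miRNA, miR-3470b, was found in more genes than miR-690, with 591. Of 14 tested miRNAs found in 5 or more genes, 3 were higher in fasted libraries, and miR-3470b itself was at -1.65 (SE 0.52; edgeR adjusted p = 0.165).

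On the principal component that held 22.1% of the variance, the control libraries lay between 0.182 and 0.298 and the fasted libraries between -0.286 and 0.00985. On the component that held 36.2%, the groups overlapped, with fasted libraries at both ends, replicate 1 at -0.552 and replicate 3 at 0.351.

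For miR-7a the log2 fold change of the 5p arm was 1.25 (SE 0.42), against -0.19 (SE 0.28) and -0.01 (SE 0.24) for the 3p arms. The log2 ratio of the 5p arm to the summed 3p arms was 12.7 ± 0.334 in control (SD, n = 3) and 13.9 ± 0.661 in fasted libraries (SD, n = 4), a difference of 1.21, with an exact permutation p of 0.0571, or 0.474 after adjustment over 136 hairpins. A general shift between dominant and minor arms is argued against by a median change of 0.032 over the other 135 hairpins, of which 2 had a larger rise. A change of both arms alike cannot be told apart from an arm-specific one: the lowest fasted ratio was 13.04 and the highest control ratio 12.90, and although separated groups had been set as evidence against it, that bound was too loose, because the exact permutation test missed its threshold. The GC content of the arms stays open too, since miR-7a lay 1.93 residual SDs above the regression on GC, between the bounds of 1 and 2 set beforehand.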
